A study of Mus musculus with 2 samples.

How the data were processed

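RNA sequencing was carried out on E14 cells, a mouse embryonic stem cell line of the 129/Ola strain, between passages 15 and 18. The cells were grown on gelatin with 15% serum and 1000 U/ml of leukemia inhibitory factor (LIF), the cytokine that keeps mouse stem cells undifferentiated through STAT3. They were transfected with a scramble siRNA or with an siRNA against Mettl8, and total RNA was taken 72 h later. The labels list 1 library per group, 2 libraries in all. The series record speaks of triplicates, but the deposited table holds 1 column per group, and no label says whether a column pools several cultures.

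The deposited values are FPKM, rounded to 2 decimals by the authors, in a table of 50508 genes named by symbol with a gene length for each. Per the submitters' processing notes, STAR 2.4.0i and featureCounts 1.5.0-p1 were used with the mm10 build. The gene annotation, the strand setting and the treatment of multiply mapped reads are not given in the sources used here. Without a known strand setting, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The deposited gene length of Mettl8, 5594 bases, equals the union of its exons in GENCODE M21 on GRCm38, the same assembly as mm10. GENCODE M21 holds 94.3% of the symbols of the table and 12918 of the 13243 with a mean FPKM of at least 1, and was used for gene type, position and GC content.

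Depth was rebuilt from the values. FPKM multiplied by gene length fell on whole multiples of 1 step in each library. Among genes shorter than 400 bases with fewer than 30 reads, 100% of 3120 and of 3560 values were whole within the rounding plus 0.005 reads. The steps correspond to denominators of 28.5 M reads for the library labelled scramble siRNA and 27.8 M for the library labelled Mettl8 siRNA. The genes of the table hold 22.2 and 21.4 M of these reads, and protein-coding genes 14.0 and 13.8 M, where M stands for 10 to the power 6. Reads per gene were rebuilt from these steps. They were used for intervals, for the simulation of counting noise and to select non-coding genes with at least 1000 reads. Differences were taken from the FPKM values. Intervals of a level are exact Poisson and intervals of a fold exact Clopper-Pearson intervals at 95%. Both cover counting error only, because reads without molecular identifiers are not independent molecules and culture-to-culture variation was not measured.

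With 1 library per group there is no residual spread, so no test between the groups was made and no p-value is given. Differences are log2(FPKM + 1) in the library labelled Mettl8 siRNA minus that in the library labelled scramble siRNA, a scale that understates the change of low genes. Genes with a mean FPKM of at least 1 over both libraries were kept, 13243 in all, and a 2-fold difference on this scale was counted as a fixed rule of size. A replicated limma analysis, foreseen for several columns per group, did not apply.

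The comparison covered 34 gene lists for pluripotency, germ layers, signalling, stress, metabolism and other cell types. For the 29 lists with at least 5 members at a mean FPKM of at least 1, the median difference was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a p-value. A median outside the central 95% of the random lists is called outside the range. Genes named in the text are Mettl8, 10 genes of the STAT3, JNK and pluripotency pathways whatever their value, the 10 largest differences each way at a mean FPKM of at least 5, and up to 4 members of each list with the largest differences. Symbols of predicted genes, clones, pseudogenes, small RNA and mitochondrial genes were left out of the largest differences. The rule also left out any symbol that begins with Rn, protein-coding genes included. Rprl2, a short non-coding RNA gene, passed this rule by its symbol. The lists, the naming rule and the first alternatives were fixed before the data were examined. The predicted, small RNA and mitochondrial RNA genes named beyond this rule were chosen after their values were seen. Under the alternatives, the direction of a named gene was compared only where its difference reached 1.5-fold, a limit also chosen after seeing the data; changes of sign without this limit are counted in the closing section.

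Counting noise was simulated with 100 Poisson draws in which each gene had the same level in both libraries. The alternatives were a pseudocount of 0.1, 2 other scalings, other filters on low values, a 1.5-fold threshold, and random lists that were unmatched, matched on GC content or gene length in 10 by 5 bins, or drawn from protein-coding genes. The steps were tested on simulated data of all 50508 genes, with 200 changed genes drawn from those with a mean FPKM of at least 5. Recovery of changed genes at lower levels was not tested. Of genes simulated at 4-fold, 99% were found at least 2-fold apart, and of those at 3-fold, 100%. Of 6200 unchanged genes with a mean FPKM of at least 5, 9 were. Of 100 unshifted lists of 20 genes, 4 lay outside the range, and 100 of 100 lists shifted by 0.2 on the log2 scale did. The largest observed list median was 0.13 in size, so recovery of shifts as small as those observed was not tested. The simulated genes varied independently and by counting noise alone, so these rates may not hold for the real lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.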

Results

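The transcriptome of E14 mouse embryonic stem cells was compared 72 h after transfection with a scramble siRNA or with an siRNA against Mettl8. The question, as the study's title states it, is how Mettl8, a target of STAT3, relates to the JNK pathway and to differentiation. Each group was represented by 1 library, so no value below has a replicate error. Of the reads held by the genes of the table, protein-coding genes took 63.0% in the library labelled scramble siRNA and 64.5% in the library labelled Mettl8 siRNA. The mitochondrial 16S ribosomal RNA gene mt-Rnr2 took 12.8% and 13.0% of the same reads. Genes with at least 1 FPKM numbered 13258 and 13321.

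Mettl8 was far higher, not lower, in the library labelled Mettl8 siRNA. Mettl8 encodes a methyltransferase that forms 3-methylcytidine in mitochondrial transfer RNA. Its level was 0.67 FPKM (0.551 to 0.812, exact Poisson interval) in the library labelled scramble siRNA. In the library labelled Mettl8 siRNA it was 100.3 FPKM (98.8 to 101.9). These levels rest on 107 and 15615 reads, a 149.8-fold difference with a counting interval of 123 to 182. Among protein-coding genes, Mettl8 ranked 10751 in the first library and 168 in the second. The gene lies on the minus strand of chromosome 2 (GRCm38, 70964561 to 71055583, ENSMUSG00000041975.17). The values of the targeted gene therefore go against the label of the siRNA library, and each direction given below is that of the library labelled Mettl8 siRNA relative to the library labelled scramble siRNA.

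**Figure D1:**
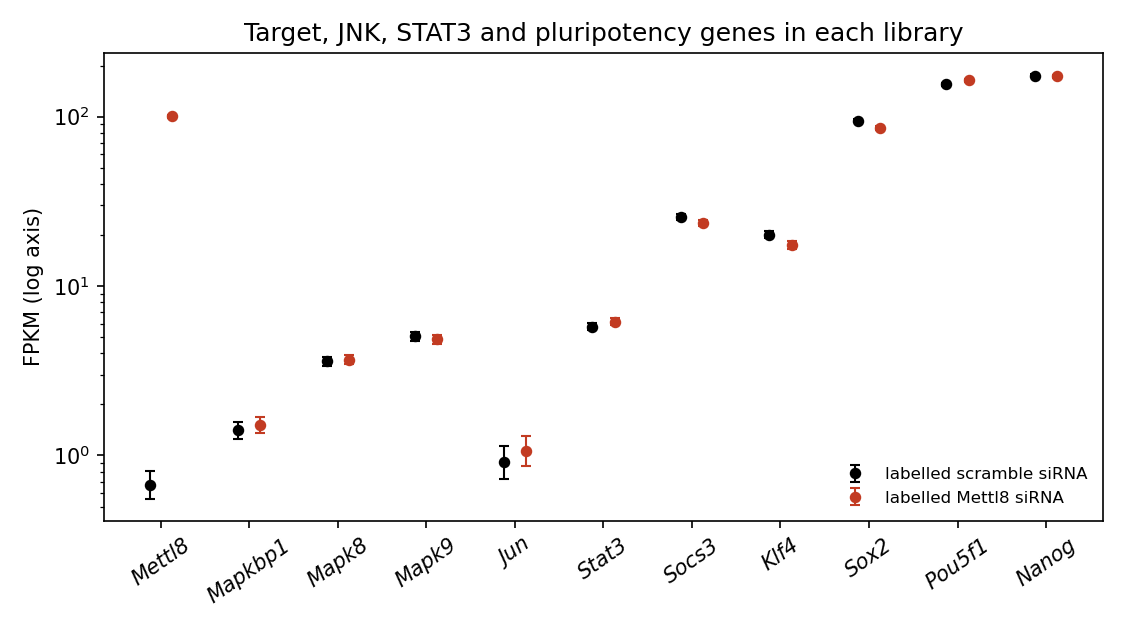
FPKM (log axis) of Mettl8 and of 10 genes of the JNK, STAT3 and pluripotency pathways in the library labelled scramble siRNA (black) and the library labelled Mettl8 siRNA (red). Points are single libraries and bars exact Poisson 95% intervals, which cover counting error only. Mettl8 stands at 0.67 and 100.3 FPKM, while each other gene has similar levels in both libraries.

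Outside Mettl8, the protein-coding transcriptomes of the 2 libraries were close. Of 9965 protein-coding genes with a mean FPKM of at least 1, 2 were at least 2-fold higher and 0 at least 2-fold lower on the log2(FPKM + 1) scale. These were Mettl8 and the predicted gene Gm11084, which is 69 bases long and had 2 and 8 reads. Across all 13243 genes, 47 were at least 2-fold higher and 38 lower. Of the 84 apart from Mettl8, 82 were shorter than 200 bases, mostly microRNA, snRNA and snoRNA genes, with a median of 10 reads over both libraries. Counting noise alone, with equal levels in both libraries, gave 73.9 such genes on average (50 to 93 in 100 draws). Their number is thus no larger than counting noise gives. Among protein-coding genes with a mean FPKM of at least 10, the standard deviation of the log2 difference without Mettl8 was 0.099, against 0.054 from counting noise. The libraries thus differed from each other beyond sampling noise, but for nearly all genes by far less than 2-fold.

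**Figure D2:**
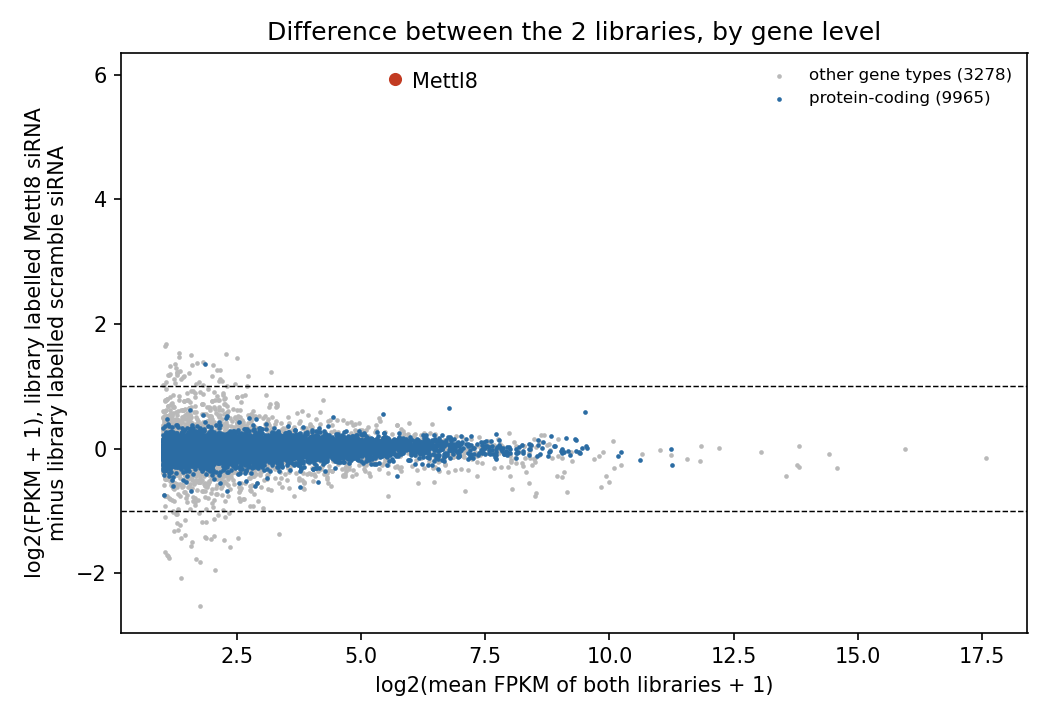
Difference in log2(FPKM + 1) between the libraries (y axis, library labelled Mettl8 siRNA minus library labelled scramble siRNA) against log2(mean FPKM + 1) (x axis) for 9965 protein-coding genes (blue) and 3278 others (grey). Dashed lines mark a 2-fold difference. Mettl8, in red, stands alone at 5.92, and the other points beyond the lines are mostly short non-coding genes of low level.

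Genes of the JNK cascade had similar transcript levels in both libraries. Transcript levels hold no measure of JNK protein or JNK activity, so whether the activity differed was not tested. Mapk8, which encodes JNK1, was 3.59 FPKM in the library labelled scramble siRNA and 3.68 in the other. Mapk9, which encodes JNK2, was 5.06 and 4.85. Mapkbp1, which encodes a JNK-binding protein, was 1.41 and 1.51 FPKM, a ratio of 1.07 (counting interval 0.915 to 1.26). Of the 29 measured members of the JNK list, 14 were higher, 15 lower and 0 differed by 1.5-fold on the log2(FPKM + 1) scale. The largest differences were 0.15 for the JNK kinase Map2k4 (9.28 and 10.4 FPKM), -0.15 for the scaffold gene Mapk8ip1, -0.13 for Map3k10 and 0.13 for Taok2 on the log2 scale. The list median was -0.021, inside the range of matched random lists. The AP-1 and immediate early genes, which include transcription factors that JNK acts on, also had a median inside the range (-0.014, 4 of 12 members higher). Jun was 0.91 and 1.07 FPKM, a ratio of 1.18 (0.863 to 1.59). The largest difference in this list was -0.25 for Zfp36, a regulator of mRNA decay.

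Pluripotency genes were abundant in both libraries. Pou5f1, the gene of OCT4, was 155 and 164 FPKM, Nanog 175 and 173, and Sox2 94.8 and 85.8. Of the 16 core pluripotency genes, 8 were higher and 8 lower, with a median of 0.010, inside the range. Utf1 was 43.5 and 36.9 FPKM and Lin28a 36.1 and 40.1, and Dppa2 was 0.20 higher on the log2 scale. The naive pluripotency factors had a median of -0.051, just below the range, with 11 of 17 members lower; it was 0.040 when each library was rescaled to the same sum. Klf2 (52.6 and 45.5 FPKM) and Klf4 (20.1 and 17.5), Kruppel-like factors of the naive state, were 0.20 and 0.19 lower on the log2 scale, and Gbx2 was 0.19 higher. Under 5 of the 9 alternative settings this list lay inside the range, so its position is not settled by these data.

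LIF and STAT3 pathway genes did not stand apart. Stat3 was 5.75 and 6.17 FPKM and its target Socs3, a feedback inhibitor of the pathway, 25.6 and 23.5. Of the 22 measured members, 10 were higher and 11 lower, and the median was -0.0020. Rhox5 was 20.4 and 24.2 FPKM and Bcl3 was 7.31 and 6.11.

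Most markers of differentiated lineages had a mean FPKM below 1 over both libraries. The mesoderm and primitive streak list had 1 of 22 members at a mean FPKM of at least 1, Bmp4 (5.26 and 6.27 FPKM), and the HOX list had 0 of 36. Trophectoderm had 4 of 17, with Tfap2c at 12.0 and 10.7 FPKM, and Tead4, Krt18 and Krt8 below 4 FPKM in both. The neuroectoderm list had 5 of 18 measured members, of which 5 were higher and 0 lower, with a median of 0.13. Nefl, a neurofilament gene, was 2.60 and 3.35 FPKM, and Pax6 was 1.06 and 1.27. Endoderm had 5 of 22, with a median of -0.098 and the laminin genes Lama1, Lamb1 and Lamc1 at log2 differences of -0.12, -0.098 and -0.094. Both lists lay inside the range, and the formative and primed epiblast list did too (0.029, with Otx2 at 4.66 and 3.86 FPKM). With random lists drawn from protein-coding genes, or matched on gene length, the neuroectoderm list lay above and the endoderm list below the range. Without the filter on low values both lay inside it, at the 71.6 percentile for neuroectoderm and 21.3 for endoderm. That setting adds the members with a mean FPKM below 1, whose differences this scale understates. It thus says little about the measured members. With GC content matched too, both lists lay inside the range, at 97.2 and 11.1. Of 24 fibroblast markers, which could mark feeder cells, 3 were measured: Fn1 (34.4 and 29.2 FPKM), Mmp2 (2.75 and 2.30) and Tagln (1.18 and 1.03).

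Of the 29 lists, 8 had a median outside the central 95% of random lists. By chance 1.45 would be expected if the genes of a list varied independently, like those of random lists. Each shift was small: the largest median in size among all 29 lists was 0.13 on the log2 scale. Of the 555 genes measured over all lists, 0 differed by 1.5-fold on the log2(FPKM + 1) scale, while the plain ratios of low genes such as Ccnd2 (1.51) and Stra8 (0.632) did exceed it. Genes of a pathway vary together, so 1.45 may be too low an expectation. Lists also share some members, so the 8 lists are not 8 independent results.

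Above the range lay 3 groups. The heat shock genes had a median of 0.12 (10 of 13 members higher, 99.8 percentile), with the chaperone genes Hsph1 at 14.8 and 18.1 FPKM, Hspd1 at 191 and 225, Chordc1 at 9.39 and 11.3, and Dnaja1 at 4.66 and 5.54. The cholesterol biosynthesis genes had a median of 0.091 (20 of 23 higher, 99.6 percentile). Fdft1, the gene of squalene synthase, was 7.71 and 9.09 FPKM, and Cyp51 5.55 and 6.21. The other METTL methyltransferase genes had a median of 0.094 (15 of 20 higher, 99.6 percentile), with Mettl6 at 4.79 and 5.67 FPKM, Mettl4 at 9.94 and 11.4, and Mettl26 at 4.12 and 3.21. Heat shock genes lay inside the range without the filter on low values (median 0.082, 97.2 percentile), and cholesterol genes did at a mean FPKM of at least 5, where their median was 0.086 (96.6 percentile).

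Beside the naive factors, 4 groups lay below the range. The replication-dependent histone genes had a median of -0.098, with 44 of 57 members lower, below each of the 10000 random lists; it was -0.0052 with each library rescaled to the same sum. These transcripts are short (median gene length 473 bases) and mostly lack a poly(A) tail, and of the 83 non-coding genes under 400 bases with at least 1000 reads, 60 were lower too, with a median of -0.093. Hist1h4i was 87.7 and 72.8 FPKM and Hist1h2ad 17.1 and 13.4. Near-identical histone genes may share reads, and the treatment of such reads is not given, so single members are uncertain. The p53 target and apoptosis genes had a median of -0.073 (20 of 23 lower, 0.05 percentile), which was 0.016 with each library rescaled to the same sum. Bbc3 (7.39 and 6.01 FPKM) encodes the pro-apoptotic PUMA, Cdkn1a (13.2 and 11.1) a cell cycle inhibitor, and Phlda3 was 28.2 and 23.9. The glycolysis and hypoxia genes had a median of -0.075 (19 of 28 lower, 0.15 percentile), which was 0.0063 after that rescaling, and included Bnip3 (23.5 and 18.7 FPKM), Aldoc (2.09 and 1.56) and Vegfa (3.54 and 2.94). The epithelial junction and EMT genes had a median of -0.11 (7 of 9 lower, 0.44 percentile), with Cldn6 at 5.65 and 4.06 FPKM, Cldn4 at 24.7 and 21.2, and Epcam at 19.5 and 16.9. The glycolysis list lay well inside the range at a mean FPKM of at least 5 (15.8 percentile). The rescaling moved the median of all genes from 0.013 to 0.096. The histone, p53, glycolysis and epithelial lists stayed below the range. The rescaling shifts the random lists as well, so it could hardly change these positions and is no separate support for them. The sum used for this rescaling depends strongly on the 57-base gene Gm23935, which alone held 33.3% and 32.1% of it.

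**Figure D3:**
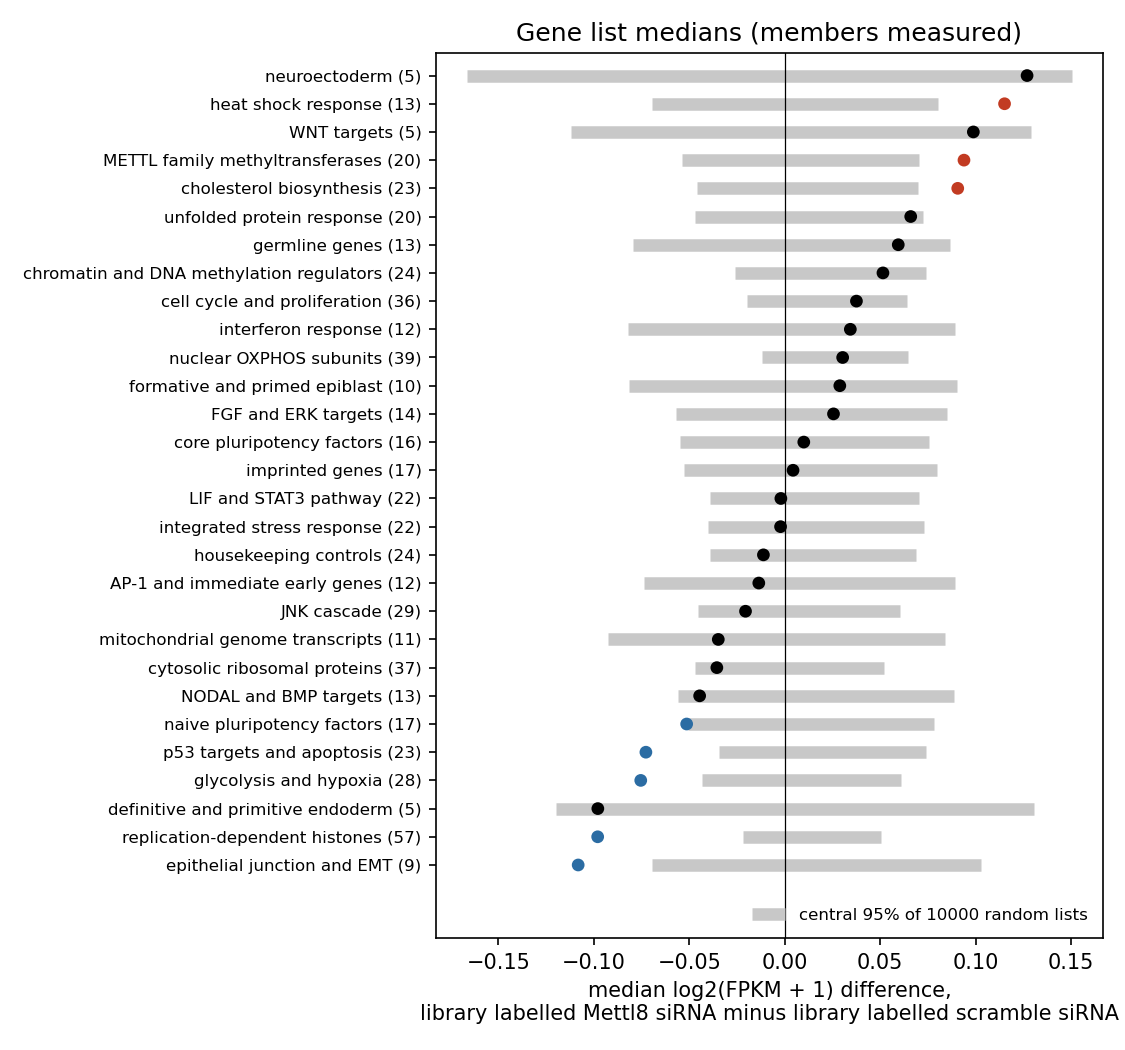
Median difference in log2(FPKM + 1) of 29 gene lists (x axis, library labelled Mettl8 siRNA minus library labelled scramble siRNA), with the number of measured members beside each name. Grey bars span the central 95% of 10000 random lists matched on expression; red points lie above, blue points below and black points inside the bar. The points span -0.11 to 0.13, and 8 lie outside their bars.

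The other signalling lists lay inside the range as reported. The FGF and ERK targets had a median of 0.026 (9 of 14 higher), but at a mean FPKM of at least 5 it was 0.118, above the range at the 99.1 percentile. The median was 0.099 (4 of 5 higher) for the WNT targets and -0.045 (6 of 13 higher) for the NODAL and BMP targets. Members of these lists with large differences include the cyclin gene Ccnd1 (10.4 and 13.0 FPKM), the ERK phosphatase gene Dusp6 (9.69 and 11.7), Id3 (4.55 and 5.90), Id4 (1.21 and 0.89) and Lefty1 (19.6 and 16.9). Interferon response genes, which double-stranded RNA can induce, had a median of 0.034 (8 of 12 higher), with Ifitm3 at 18.0 and 14.3 FPKM. The integrated stress response median was -0.0022, with Ddit4 at 20.6 and 15.9 FPKM. The unfolded protein response median was 0.066 (16 of 20 higher), with the chaperone gene Hspa5 at 102 and 117 FPKM and Calr at 73.4 and 83.1.

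Mitochondrial and growth-related lists also lay inside the range as reported. The 11 measured protein-coding transcripts of the mitochondrial genome had a median of -0.035, with mt-Co1 at 1200.4 and 1106 FPKM; with random lists matched on GC content too, this list lay below the range, at the 0.6 percentile. The levels of mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 were at most 3 FPKM, and mt-Co1 exceeded mt-Co2 476-fold and 469-fold; the nuclear genome holds near-identical copies of this stretch, so these values are uncertain. The nuclear OXPHOS genes had a median of 0.030, with Ndufa10 at 8.49 and 10.1 FPKM. The median was -0.036 for cytosolic ribosomal protein genes (28 of 37 lower, Rps20 at 159 and 144 FPKM), and 0.038 for cell cycle genes (25 of 36 higher, Ccnd2 at 1.18 and 1.78, Ccne1 at 42.8 and 48.3). For chromatin regulators it was 0.051, with the Polycomb genes Ezh2 at 12.7 and 15.2 FPKM and Eed at 22.9 and 25.7. Ribosomal protein genes lay below the range when random lists were drawn from protein-coding genes (0.09 percentile) or matched on gene length (0.21 percentile), and without the filter on low values. The medians were 0.059 for germline genes (7 of 13 higher, Stra8 at 1.33 and 0.84 FPKM), 0.0043 for imprinted genes (Mest at 15.1 and 17.3) and -0.011 for the 24 measured housekeeping controls (11 higher, 13 lower). The 2-cell-like list had 3 of 22 measured members, Eif1a, Zfp809 and Zscan4a, at log2 differences of 0.16, 0.072 and -0.19.

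Beyond Mettl8, and with symbols of predicted, small RNA and mitochondrial genes, clones and pseudogenes left out, the largest differences among genes with a mean FPKM of at least 5 lay between -0.53 and 0.50 on the log2 scale. The genes that were higher were led by Nudt2, a nucleotide hydrolase gene (4.57 and 6.85 FPKM, counting interval of the ratio 1.17 to 1.93), and Immp1l, a mitochondrial inner membrane peptidase gene (5.19 and 7.64, ratio 1.47, 1.18 to 1.84). Rprl2, Med11, Zcchc10, Tmx2, Ccdc124, Nqo1, Pin4 and Psmg4 followed, with log2 differences from 0.40 down to 0.33. The lower genes were led by 2 cytochrome c oxidase subunit genes, Cox6b2 (19.8 and 13.4 FPKM, ratio 0.676, 0.595 to 0.766) and Cox7a1 (6.50 and 4.23, ratio 0.651, 0.467 to 0.902). Ppp1r35, Rpl28, Platr11, Tmsb15b2, Ubqln2, Pdcd4, Erdr1 and Rps27rt followed, from -0.47 to -0.36. Of all protein-coding genes with a mean FPKM of at least 5, 2 were at least 1.5-fold lower on this scale. Both have symbols that the rule left out. Rpl28, Tmsb15b2, Erdr1 and Rps27rt have near-identical copies elsewhere in the genome and are uncertain. Without replicates, none of these differences can be set against the spread between cultures.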

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

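The alternatives with GC content, gene length or protein-coding genes were chosen after seeing the data, and the others before. Mettl8 was higher under each setting, at 5.92 as reported, 7.03 with a pseudocount of 0.1 and 6.38 with each library rescaled to the same sum. The 47 genes at least 2-fold higher and 38 lower became 95 and 81 with a pseudocount of 0.1, 94 and 70 without a filter, 4 and 1 at a mean FPKM of at least 5, 141 and 139 at 1.5-fold, and 2 and 0 among protein-coding genes. The other 2 scalings kept both counts within 1.5 times. The number of lists outside the range stayed between 6 and 11 of those tested, against 8. The other 2 scalings shift lists and random lists alike, so they could change this number little. Of these 8, the naive pluripotency list was lost under 5 settings, glycolysis and cholesterol at a mean FPKM of at least 5, and heat shock without a filter, where 34 lists were tested; the cause was not tested. The 57-base gene Gm23935 alone held 33.3% of the FPKM sum in the library labelled scramble siRNA and 32.1% in the other. Scaling by this sum thus depends strongly on 1 very short gene. Rescaling to the same sum shifted the median of all genes from 0.013 to 0.096. The rescaling thus adds a shift common to all genes, which turns small negative values positive by itself. It turned the medians of the naive pluripotency (0.040), p53 (0.016) and glycolysis (0.0063) lists above 0, as it did for several lists inside the range, among them JNK and LIF, and moved 29 of 148 named genes beyond their counting interval. Of the 148, 3 changed sign under it and 1 with the median ratio set to 0. Most of the 148 were named for large differences, so few could change sign. The number of all genes that changed sign was not counted, so these counts say nothing about genes with small differences. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Few reads limit the genes 2-fold apart, Jun (83 and 95 reads) and other low named genes, among them Id4 (57 and 41) and Rps27rt (66 and 48). The counting intervals of the ratio, 0.480 to 1.12 for Id4 and 0.502 to 1.10 for Rps27rt, include equal levels. For genes with many more reads the limit is the missing replicate.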

Other observations

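Most of the abundant snRNA genes were lower in the library labelled Mettl8 siRNA, while snRNA and snoRNA genes as a whole had no common direction. Of all 127 snRNA genes, 61 were higher and 66 lower, with a median log2 difference of -0.089, and of 341 snoRNA genes 177 were higher and 164 lower, with a median of 0.021. Of the 7 snRNA genes with a mean FPKM of at least 100, a limit chosen after the values were seen, 6 were lower, with a median of -0.64. The lower ones include Gm24265 (698 and 430 FPKM, 141 bases) and Gm25360 (1202 and 832 FPKM, 191 bases). Gm24407 is also 141 bases long, and Gm22973 and Gm26316 are also 191 bases long. Whether genes of equal length are copies that share reads was not tested, so the 6 may not be separate results. The snoRNA genes Snord17 (456 and 280 FPKM) and Rnu3a (563 and 417), which act in ribosomal RNA processing, and Rmrp (15273 and 12707), the RNA of RNase MRP, were lower too. Rn7sk (14341 and 14762), the RNA that holds back the elongation factor P-TEFb, was not, and the snoRNA genes Snord33 (229.6 and 273 FPKM) and Snord34 (260.0 and 281) were higher. Over 83 non-coding genes under 400 bases with at least 1000 reads, 60 were lower and the median was -0.093. Over 173 longer non-coding genes with as many reads, 73 were lower and the median was 0.018. These values come from 2 libraries without replicates.

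The transfer RNAs of the mitochondrial genome include the known substrates of the Mettl8 enzyme. Of the 18 measured of 22, 12 were higher and 6 lower, with a median of 0.021, between -0.36 and 0.38. The threonine transfer RNA gene mt-Tt was 71.3 and 72.4 FPKM (ratio 1.02, counting interval 0.794 to 1.30), and mt-Ts1 rested on 8 and 10 reads. A table of levels holds no measure of methylation. Among abundant genes, the predicted genes Gm10800 (582 and 873 FPKM), Gm10801 (83.3 and 132) and Gm21738 (34.1 and 50.5) were higher by 0.58, 0.66 and 0.56 on the log2 scale. Whether these predicted genes share reads was not tested, so they may not be separate results.

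The tests of Mettl8 below, and those with random lists matched on GC content or gene length, were chosen after the results were seen. The targeted gene was 149.8-fold higher in the library labelled with its siRNA. A gain of the chromosomal region is argued against, because the 10 nearest measured genes, within 505001 bases, had a median difference of 0.051 (-0.091 to 0.26), and the overlapping gene Dcaf17 was 2.78 and 2.90 FPKM. Swapped labels of the 2 libraries stay open: the library labelled scramble siRNA holds 0.668% of the other's Mettl8, as a very strong knockdown might, and no value apart from Mettl8 tells which library received the siRNA. A Mettl8 expression construct, or the siRNA itself being sequenced, stays open as well: 0 other protein-coding genes with a mean FPKM of at least 5 were 2-fold apart, and gene totals do not hold the read positions that would tell these apart.

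The 8 lists outside the range could reflect a technical difference between the libraries. A GC trend was present: the median log2 difference of protein-coding genes with a mean FPKM of at least 5 went from 0.062 in the lowest of 4 equal groups by GC content to -0.019 in the highest. However, 8 of the 8 lists stayed outside on the same side with random lists matched on GC content too, and 8 did with gene length matched, which argues against either as the whole cause. Differences between cultures, in RNA handling or in the transfection stay open, since 1 library per group gives no spread to set the shifts against.

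The 84 genes at least 2-fold apart other than Mettl8 are consistent with counting noise. This number lies within the 50 to 93 genes that 100 draws with equal levels gave. No biological explanation was tested for them.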
